A study of Mus musculus with 12 samples.

How the data were processed

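The series holds 12 single-colour Affymetrix 3' arrays of 3T3-L1 adipocytes, 3 for each of 4 groups: DMSO and 5 µM berberine for 3, 6 or 12 h. Per the labels' protocols, the cells were induced for 48 h with 5 µg/ml insulin, 1 µM dexamethasone and 0.5 mM IBMX, used at days 8 to 10 and kept in serum-free medium with 0.2% albumin for 12 h before treatment. Groups and replicate numbers came from the labels.

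The deposited values are log2 signals, 1 column per array, of 45101 probe sets, 64 of them controls. MAS5 is named in the submitters' processing notes, with its version not given in the sources used here. In the values, the 2% trimmed mean of the linear signal was 500.004 on every array, and signals under 1 appeared to have been raised to 1. MAS5 scales each array by 1 factor, so a bias that differs with brightness is left in, and its dim values are noisy on the log2 scale. Detection calls were not used here. Scanner files were not analysed here.

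The detection threshold was the median of the log2 values of all non-control probe sets, 5.77 (a linear signal of 54.6), and a probe set was kept where at least 3 of 12 arrays reached it, which left 25053. Gene names came from the platform annotation, updated through Entrez identifiers with RefSeq's gene table, which was used for names only. Of the 45037 non-control probe sets, 34945 had 1 symbol, 932 had several and 9160 had none; 34741 matched through the identifier and 0 symbols changed. Each gene was represented by its kept probe set with the highest mean, and by one ending in _x_at, which can bind transcripts of several genes, only where it had no other (104 genes). This gave 12136 genes of the 18193 on the array, 5611 of them with more than 1 kept probe set. A call for a gene is therefore the call of a single probe set.

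Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group over all 12 arrays, 8 residual degrees of freedom, eBayes with an intensity trend, two-sided) and adjusted over the genes tested by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The contrasts were each berberine time against DMSO, the 3 pairs of berberine times, and the moderated F test over the contrasts with DMSO. Fold changes are ratios of geometric mean signals, and SE is limma's standard error. Where 1 group mean lay under the threshold, a bound is given as at least N-fold, computed with values under the threshold raised to it. Lists were tested with limma's camera at a preset correlation of 0.01 between members, adjusted over the 31 lists with at least 5 tested members, and again with the correlation estimated for each list. Members were also adjusted over the list alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

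The groups, tests, alternatives, 20 single genes and 32 gene lists were fixed before the data were examined. The result of 1 of the single genes is not reported here. The lists held 636 genes, all matched to a current symbol, of which 552 were tested, and some genes stand on more than 1 list. They covered the integrated stress response, endoplasmic reticulum chaperones, heat shock, oxidative stress (NRF2), p53, NF-kB and interferon-stimulated genes; glycolysis, hypoxia (HIF), oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, lipolysis, branched-chain amino acid breakdown, insulin signalling and AMPK genes; mature adipocyte, adipokine, fibroblast, macrophage, endothelial and brown or beige adipocyte markers; and cell cycle, clock, immediate early, glucocorticoid, autophagy, ribosomal protein, ribosome biogenesis and aryl hydrocarbon receptor genes.

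Named genes followed a rule fixed at the same time. For each contrast with DMSO it took the 10 largest rises and 10 largest falls with both group means at or above the threshold and no overlap between the groups, up to 4 further genes per direction given as bounds, up to 4 members per list with the largest change, and the single genes. For contrasts between berberine times it took the 5 largest rises and falls. Symbols of predicted and RIKEN genes were left out. Some genes that the rule allows were left out of the results for space, among them genes with another probe set of opposite sign or a call that ended when 1 array was left out; the values of those with an opposite probe set are given with the dependence on the processing.

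On data simulated for 12 h against DMSO (12136 genes, 200 changed, 20 runs), limma recovered 43.9% of changes of 0.5 on the log2 scale, 72.2% of changes of 1 and 88.2% of changes of 2, and 5.12% of calls were false. A simulated shift of -0.5 of the HIF list was found by camera in 20 of 20 runs, with 1 unshifted list called in total. The gene runs changed 200 genes, while 3426 were called at 12 h in the data, so the shares recovered there may differ. The simulated genes were drawn independently of each other, so these runs do not check list calls where members are correlated. In the data the estimated correlation between members was 0.105 for the HIF list and 0.658 for ribosomal proteins. Alternatives were quantile normalization, no filter, a filter at the 75th percentile (8.60), a pseudocount of 16, dim values raised to the threshold, no intensity trend, the replicate number as a block, the mean of a gene's probe sets, all kept probe sets, only the 2 groups compared, and leaving out each array. Overlaps between times were set against 100 simulations of unchanged groups that share the DMSO arrays. Probe sets with no symbol or several stayed out of the gene tests.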

Results

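Expression was measured on 12 single-colour oligonucleotide arrays of 3T3-L1 adipocytes, fat cells made from a mouse fibroblast line with insulin, dexamethasone and IBMX. At days 8 to 10 after differentiation the cells spent 12 h in serum-free medium with 0.2% albumin. They then received the solvent DMSO or 5 µM berberine, a plant alkaloid, for 3, 6 or 12 h, with 3 arrays per group. The labels give the expression changes brought about by this treatment as the question. The duration of the DMSO incubation is not given in the labels, so each berberine time was set against the same 3 DMSO arrays. The contrasts with DMSO therefore do not separate an effect of berberine from one of time in culture. Between 47.9% and 51.6% of the probe sets of an array lay at or above the detection threshold. As the threshold is the median of all values, the mean share is 50% by construction and is no detection rate. The correlation of arrays across probe sets, which are not independent replicates, was 0.968 to 0.976 over the 12 pairs within groups and 0.956 to 0.974 over the 54 pairs between groups. The 3'-to-5' difference of control probe sets, a sign of RNA integrity, lay between -0.16 and 0.03 on the log2 scale for Gapdh and between 1.51 and 1.72 for actin. Spike controls were brighter at 6 h than with DMSO, with log2 signals of 15.14 to 15.40 against 14.78 to 15.11 for creX and 10.38 to 10.56 against 10.10 to 10.31 for bioB. Their means were also higher at 3 and 12 h, where the ranges overlapped those of DMSO. For creX these means were 15.09 and 15.17 against 14.95, and for bioB 10.36 and 10.38 against 10.22. The first principal component held 18.6% of the variance. With 3 arrays per group their number limits the precision, and because the labels do not say that they came from separate cultures, the p-values measure only the spread between these samples, which may be technical. Of 12136 genes tested, 3045 (25.1%) differed among the 4 groups by limma's moderated F test.

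**Figure D1:**
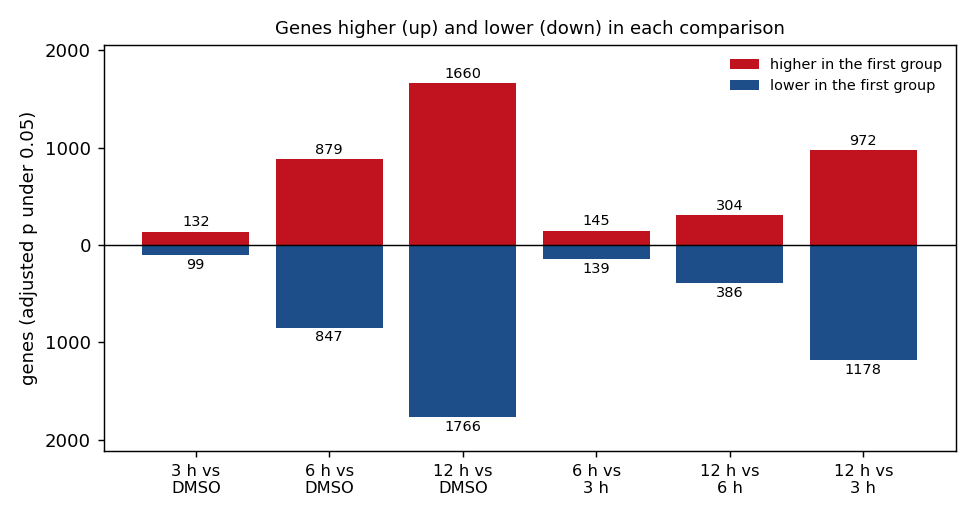
Number of genes with an adjusted p under 0.05 (vertical axis) in each comparison (horizontal axis), with bars upward for genes higher and downward for genes lower in the group named before "vs". Against DMSO the bars grow from 132 higher and 99 lower genes at 3 h to 1660 higher and 1766 lower genes at 12 h.

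After 3 h of berberine, some genes of the integrated stress response and of inflammation were higher and some genes controlled by hypoxia-inducible factors (HIF) were lower than with DMSO. None of the 3 passed as a list with an estimated correlation between members (adjusted p = 0.194, 0.0851 and 0.0851). Atf3, a stress-induced transcription factor, rose 2.28-fold (log2 change 1.19 ± 0.21 SE, adjusted p = 0.00485), and Chac1, a glutathione-degrading enzyme, rose 2.13-fold. Ddit3, the transcription factor CHOP, rose 1.78-fold, from a log2 signal of 11.79 ± 0.02 to 12.63 ± 0.07 (SD, n = 3). Gadd45a, a growth arrest and DNA damage gene, rose 2.16-fold. The cytokine gene Il6 rose 2.05-fold (adjusted p = 0.0122, or 0.0593 and 0.0609 without 3 h replicates 2 and 3) and the chemokine genes Cxcl1, Ccl2 and Ccl7 rose 1.83-fold, 1.74-fold and 1.63-fold. With DMSO the log2 signals of Atf3 (5.77 to 6.63) and Il6 (5.88 to 6.29) lay near the threshold of 5.77. Folds of these genes at every time start from there. Ankrd37, a HIF target, was 5.66-fold lower (log2 change -2.50 ± 0.23 SE, adjusted p = 8.46e-06), falling from a log2 signal of 9.15 ± 0.19 to 6.65 ± 0.28 (SD, n = 3).

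In all, 231 genes changed at 3 h, 132 higher and 99 lower, and 12 of them by at least 1 on the log2 scale. All 231 had 3 berberine arrays on one side of all 3 DMSO arrays, which held for 2310 of all genes tested, while chance gives 10%. Rises also took in Nfkbie, an inhibitor of NF-kB (1.95-fold), Tlr2, an innate immune receptor (1.82-fold), and Flcn, the folliculin gene of lysosomal signalling (1.79-fold). Falls took in Dusp6, a phosphatase of ERK (2.32-fold lower, adjusted p = 0.00806, or 0.0637 without DMSO replicate 1), and Spry4, an inhibitor of growth factor signalling (1.94-fold). Ppp1r3b and Ppp1r3c, subunits that bring protein phosphatase to glycogen, were 2.24-fold and 1.89-fold lower, and Ffar4, a receptor for long-chain fatty acids, was 2.02-fold lower. Narf was 2.25-fold lower in the probe set used and had a log2 change of 0.33 in another (adjusted p = 0.907). Ccl20, a chemokine gene under the threshold in DMSO cells, was at least 1.64-fold higher (adjusted p = 0.00441, or 0.107 with dim values raised to the threshold). Such bounds set the mean of the brighter group against the dimmer group with its values raised to the threshold. Taf15 (log2 change 1.02) and Klf5 (0.87) also passed the test, but depended on single arrays. The adjusted p of Taf15 was 0.226 and 0.0701 without DMSO replicates 1 and 3 and 0.0579 and 0.184 without 3 h replicates 1 and 3. That of Klf5 was 0.182 and 0.127 without DMSO replicates 1 and 2 and 0.163, 0.146 and 0.0946 without 3 h replicates 1, 2 and 3.

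Among the gene lists chosen before the data were examined, 6 moved up and 3 moved down at 3 h by limma's camera test. With an estimated correlation between members 0 of 31 lists passed camera (7 at an unadjusted p under 0.05). Of 34 integrated stress response genes, 7 rose and 1 fell (11 and 1 adjusted over the list alone), with an adjusted p of 2.54e-06 for the list (adjusted p = 0.194 with an estimated correlation). The member that fell was Ddit4, an inhibitor of mTORC1 (1.80-fold). Of 19 HIF targets, 6 fell (12 adjusted over the list alone), among them Egln3, an oxygen-sensing prolyl hydroxylase (1.59-fold). HIF targets as a list had an adjusted p of 6.04e-09, and adjusted p = 0.0851 with an estimated correlation. In glycolysis and glucose transport, 2 of 17 genes fell (4 adjusted over the list alone). Glycolysis genes as a list had an adjusted p of 0.000533, and adjusted p = 0.194 with an estimated correlation. The glucose transporter gene Slc2a1 was 1.43-fold and the hexokinase gene Hk2 1.42-fold lower. NF-kB and inflammatory genes rose in 6 of 19 cases (13 adjusted over the list alone). NF-kB genes as a list had an adjusted p of 7.75e-08, and adjusted p = 0.0851 with an estimated correlation. Heat shock proteins moved down (adjusted p = 0.035, and adjusted p = 0.189 with an estimated correlation), with 1 of 15 called (3 adjusted over the list alone), Hspa1b, which was 1.31-fold lower. The p53 targets moved up (adjusted p = 0.035, and adjusted p = 0.189 with an estimated correlation), with 3 of 19 risen (4 adjusted over the list alone). Clock genes moved up (adjusted p = 0.029, and adjusted p = 0.44 with an estimated correlation), with 2 of 17 risen (2 adjusted over the list alone). Nr1d2, a repressor of the clock, rose 1.39-fold and Dbp, a clock output gene, 1.37-fold. For Dbp the adjusted p was 0.0175, but 0.0653 and 0.0594 without DMSO replicates 1 and 3 and 0.0718 and 0.0954 without 3 h replicates 1 and 2. Autophagy and lysosome genes moved up (adjusted p = 0.0172, and adjusted p = 0.194 with an estimated correlation), with 3 of 23 risen (6 adjusted over the list alone). For cytosolic ribosomal proteins the list moved up with 0 of 13 members called (0 adjusted over the list alone), and quantile normalization ended its call (adjusted p = 0.567). Ribosomal proteins as a list had an adjusted p of 0.00703, and adjusted p = 0.67 with an estimated correlation. Median, mean and test differed in sign for the uncalled lists of the tricarboxylic acid cycle, fatty acid oxidation, macrophage markers and aryl hydrocarbon receptor targets.

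At 3 h the count of genes fell from 231 to 117 without DMSO replicate 1, and to 137 without replicate 1 and 126 without replicate 2 of the 3 h group. It was 93 without the intensity trend and 114 with the mean of each gene's probe sets. Without the trend the adjusted p was 0.0643 for Atf3, 0.0583 for Nfkbie, 0.0531 for Cxcl1, 0.0962 for Ccl7 and 0.0733 for Flcn. It was 0.0663 for Ddit4, 0.0796 for Hk2, 0.0706 for Egln3, 0.132 for Dbp, 0.223 for Taf15 and 0.071 for Klf5. With the mean of probe sets it was 0.0806 for Ddit3, 0.14 for Nfkbie, 0.153 for Narf and 0.162 for Spry4. List calls ended without DMSO replicate 1 for heat shock (adjusted p = 0.0965), clock (0.064) and ribosomal genes (0.0965), and without DMSO replicate 3 for heat shock (0.0617), p53 (0.0595) and autophagy genes (0.0617). They also ended without 3 h replicate 1 for ribosomal genes (0.0562), and without 3 h replicate 2, which left 5 lists, for heat shock (0.0794), p53 (0.0759), clock (0.0602) and autophagy genes (0.0615).

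After 6 h many genes of the integrated stress response and some of cholesterol synthesis were higher than with DMSO, and some genes of insulin signalling and HIF were lower. As lists these did not pass with an estimated correlation (adjusted p = 0.065, 0.499, 0.164 and 0.0687). Atf3 rose 5.30-fold (log2 change 2.41 ± 0.21 SE, adjusted p = 1.2e-06). Trib3, a pseudokinase that inhibits AKT, rose 3.84-fold (1.94 ± 0.10), and Ddit3 rose 3.70-fold (1.89 ± 0.06). Atf4, the transcription factor of this response, rose 2.60-fold, and Slc7a11, the cystine transporter, rose at least 3.10-fold (adjusted p = 0.000301). Il6 rose 2.44-fold and Hmox1, the heme oxygenase, 2.08-fold. Ankrd37 was 5.10-fold lower (-2.35 ± 0.23, adjusted p = 3.82e-06), Egln3 was 2.53-fold lower (-1.34 ± 0.11), and the genes of the lactate and niacin receptors, Hcar1 and Hcar2, were 2.88-fold and 2.65-fold lower.

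In total 1726 genes changed at 6 h, 879 higher and 847 lower, 78 of them by at least 1 on the log2 scale. In 1676 of them the groups did not overlap, as in 3634 of all genes tested, with 10% given by chance. Gadd45a was 3.35-fold, Chac1 2.73-fold and Mex3b, an RNA-binding ubiquitin ligase, 2.46-fold higher. Among the falls were Narf (3.08-fold), Ak4, a mitochondrial adenylate kinase (3.01-fold), Ffar4 (2.76-fold) and Spry4 (2.56-fold, or adjusted p = 0.116 with the mean of probe sets), and Eppk1, under the threshold in berberine cells, was at least 2.85-fold lower (adjusted p = 0.00268).

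Of the lists, 9 moved up and 4 moved down at 6 h, and 0 of 31 passed with an estimated correlation by camera (7 at an unadjusted p under 0.05). In the integrated stress response 24 of 34 genes rose and 1 fell (24 and 1 adjusted over the list alone). Stress response genes as a list had an adjusted p of 9.08e-20, and adjusted p = 0.065 with an estimated correlation. Cholesterol synthesis genes rose in 9 of 20 cases (11 adjusted over the list alone), among them Cyp51, a sterol demethylase (1.55-fold), and Mvd, a mevalonate pathway enzyme (1.43-fold). Cholesterol genes as a list had an adjusted p of 0.000298, and adjusted p = 0.499 with an estimated correlation. NF-kB genes rose in 11 of 19 cases (11 adjusted over the list alone), with Cxcl1 at 1.82-fold and Ccl2 at 1.68-fold. NF-kB genes as a list had an adjusted p of 1.67e-05, and adjusted p = 0.113 with an estimated correlation. Interferon-stimulated genes rose in 7 of 19 cases (8 adjusted over the list alone). Interferon-stimulated genes as a list had an adjusted p of 0.0027, and adjusted p = 0.499 with an estimated correlation. Ifit3, an antiviral gene, had a log2 change of 1.00 (adjusted p = 0.013, or 0.0747 without 6 h replicate 3, 0.0596 without DMSO replicate 2 and 0.0943 without the intensity trend). The list itself lost its call without 6 h replicate 3 (adjusted p = 0.0652). The p53 targets rose in 7 of 19 cases (7, with 1 fallen, adjusted over the list alone), with the kinase gene Plk2 at 1.69-fold. The p53 targets as a list had an adjusted p of 0.00768, and adjusted p = 0.113 with an estimated correlation. Clock genes rose in 6 of 17 cases (7 adjusted over the list alone), with Dbp at 1.90-fold and the repressor gene Cry1 at 1.69-fold. Clock genes as a list had an adjusted p of 0.00277, and adjusted p = 0.239 with an estimated correlation. Of 23 autophagy and lysosome genes, 9 rose and 1 fell (12 and 1 adjusted over the list alone), with Fnip1, a folliculin partner, at 1.44-fold and Gabarapl1, an autophagosome protein, at 1.39-fold. Autophagy genes as a list had an adjusted p of 0.00277, and adjusted p = 0.113 with an estimated correlation.

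HIF targets fell in 12 of 19 cases at 6 h (13 adjusted over the list alone; list adjusted p = 1.36e-08, adjusted p = 0.0687 with an estimated correlation). Glycolysis genes fell in 8 of 17 cases (11 adjusted over the list alone; list adjusted p = 4.34e-05, adjusted p = 0.14 with an estimated correlation). Hk2 was 1.70-fold, Slc2a1 1.57-fold and the pyruvate kinase gene Pkm 1.39-fold lower. Of 21 insulin signalling and FOXO genes, 10 fell and 2 rose (13 and 2 adjusted over the list alone), with the insulin receptor substrate genes Irs2 and Irs1 at 1.74-fold and 1.44-fold lower. Insulin and FOXO genes as a list had an adjusted p of 0.000384, and adjusted p = 0.164 with an estimated correlation. In lipolysis and lipid droplet proteins 4 of 12 fell and 2 rose (6 and 2 adjusted over the list alone). Lipolysis genes as a list had an adjusted p of 0.0178, and adjusted p = 0.282 with an estimated correlation. Cidec, a lipid droplet fusion protein, was 1.55-fold lower. Fabp4, a fatty acid carrier, had a log2 change of 0.29 (adjusted p = 0.023), but 0.00 after quantile normalization and -0.75 (adjusted p = 0.0217) and -0.57 in its other probe sets. The call of the lipolysis list ended without DMSO replicate 3 (adjusted p = 0.101) or 6 h replicate 1 (0.0519). Ribosomal protein genes rose in 10 of 13 cases (12 adjusted over the list alone), a call that ended with quantile normalization (adjusted p = 0.286). Ribosomal proteins as a list had an adjusted p of 1.73e-05, and adjusted p = 0.37 with an estimated correlation. Oxidative phosphorylation subunits moved up with 2 of 46 risen (1 adjusted over the list alone). Respiratory subunits as a list had an adjusted p of 0.0165, and adjusted p = 0.688 with an estimated correlation. Their mean change of 0.08 turned to -0.03 after quantile normalization (adjusted p = 0.194). The call ended without DMSO replicate 1 (0.0695), DMSO replicate 2 (0.118) or 6 h replicate 2 (0.218), and Cox6a1 was 1.34-fold higher. Mature adipocyte markers did not pass at 6 h (adjusted p = 0.195; 4 rose and 6 fell of 17, 4 and 7 adjusted over the list alone). Quantile normalization added falls of this list (adjusted p = 0.00978), fatty acid synthesis (0.0117) and branched-chain amino acid breakdown (0.0278). Among the adipocyte markers the adiponectin gene Adipoq had a log2 change of 0.33 (adjusted p = 0.0325, or 0.721 after quantile normalization) and Pparg, the master regulator of fat cells, 0.21 (adjusted p = 0.041, or 0.0636). The call of Adipoq ended without DMSO replicates 1 and 2 (0.156 and 0.126) or 6 h replicates 1, 2 and 3 (0.0516, 0.131 and 0.0642). That of Pparg ended without DMSO replicates 1, 2 and 3 (0.0724, 0.126 and 0.0582) or 6 h replicates 1 and 2 (0.137 and 0.182). Median, mean and test differed in sign for the uncalled adipokine, macrophage and glucocorticoid lists. The gene count was 1116 without DMSO replicate 1, 1140 without 6 h replicate 2 and 1099 with the mean of each gene's probe sets.

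At 12 h many integrated stress response, oxidative stress and interferon-stimulated genes were higher, and many genes of lipolysis and of the mature adipocyte were lower. As lists these did not pass with an estimated correlation (adjusted p = 0.106, 0.106, 0.153, 0.125 and 0.153). Atf3 rose 9.38-fold (log2 change 3.23 ± 0.21 SE, adjusted p = 9.62e-09), Trib3 5.78-fold (2.53 ± 0.10), Ddit3 5.34-fold (2.42 ± 0.06) and Hmox1 5.24-fold (2.39 ± 0.11). Ifit3 rose 3.62-fold (1.86 ± 0.25). Pck1, the enzyme of glyceroneogenesis and gluconeogenesis, was 4.76-fold lower (-2.25 ± 0.16), from a log2 signal of 10.06 ± 0.24 to 7.80 ± 0.33 (SD, n = 3), and Cidec was 2.70-fold lower (-1.44 ± 0.07).

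**Figure D2:**
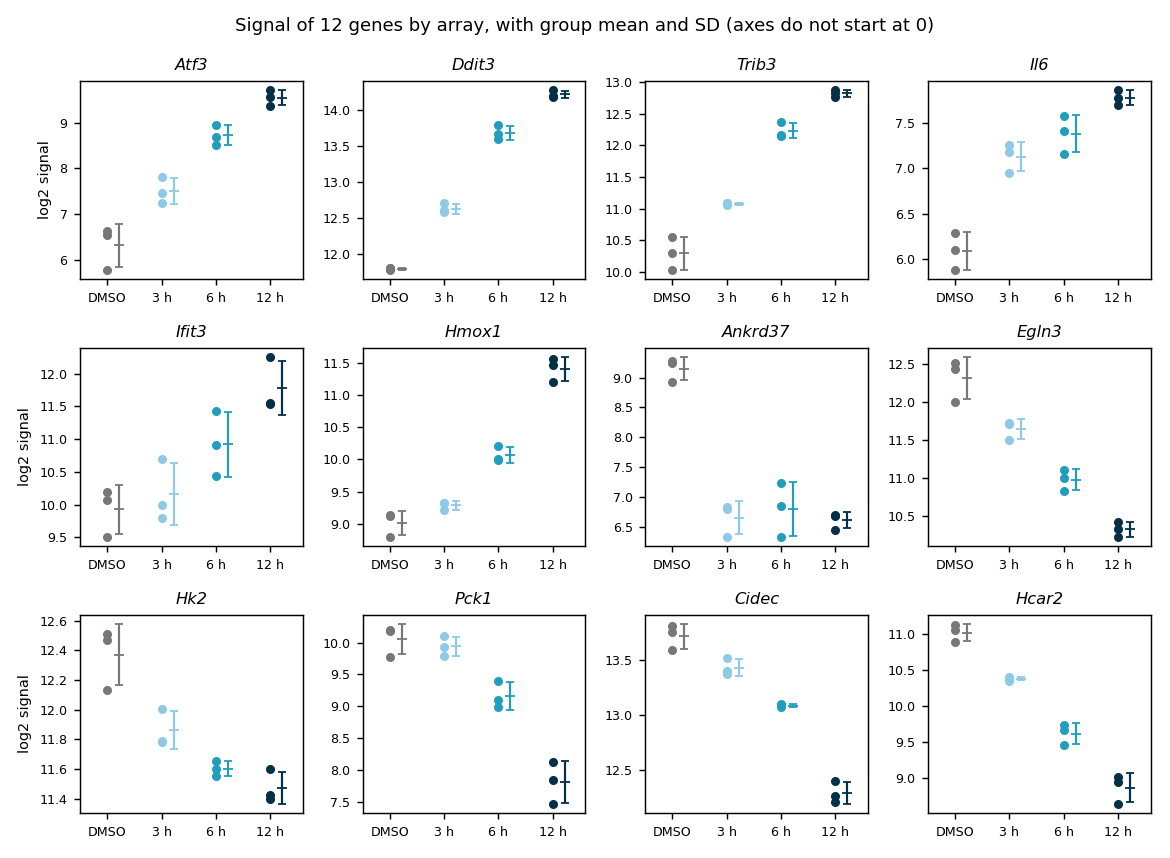
Log2 signal (vertical axes, which do not start at 0) of single arrays (points) for 12 genes with DMSO and with berberine for 3, 6 and 12 h (horizontal axes), with group means and SDs as bars (n = 3). Mean Ddit3 signal goes from 11.79 with DMSO to 14.21 at 12 h, and mean Ankrd37 signal from 9.15 to 6.61.

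There were 3426 genes changed at 12 h, 1660 higher and 1766 lower, with 117 higher and 186 lower by at least 1 on the log2 scale. Groups did not overlap for 3277 of them, nor for 4780 of all genes tested, of which chance gives 10%. Beyond the genes already given for 12 h, the largest rises by the naming rule were those of Mreg, a melanosome transport protein (4.46-fold), Taf15, an RNA-binding protein (4.17-fold), and Gadd45a (3.98-fold). Stbd1, a glycogen-binding protein, rose 3.81-fold and Ppp1r15a, a phosphatase subunit that reverses the stress-induced block of translation, 3.33-fold, and Slc7a11 rose at least 4.13-fold. Besides Pck1, the largest falls by the same rule were those of Ankrd37 (5.83-fold), Ankef1 (5.13-fold, with a log2 change of -0.17 in another probe set), Aatk, a kinase (4.64-fold), and Hcar2 (4.45-fold). Rasd1, a dexamethasone-induced RAS protein, was 4.20-fold, Egln3 3.97-fold, Spry4 3.81-fold (with -0.01 in another probe set) and Ffar4 3.77-fold lower. Pi15 had a log2 change of -1.89 (adjusted p = 0.00962), but 0.48 in another probe set. Genes under the threshold after berberine were B3galt2, a galactosyltransferase (at least 7.08-fold lower), Hcar1 (at least 5.25-fold lower), Eppk1 (at least 2.98-fold lower) and Spon2 (at least 2.79-fold lower).

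Of 31 lists, 8 moved up and 9 moved down at 12 h, and 0 of them passed with an estimated correlation by camera (9 at an unadjusted p under 0.05). In the integrated stress response 24 of 34 genes rose and 1 fell (24 and 1 adjusted over the list alone), the fallen member again being Ddit4 (2.04-fold). Stress response genes as a list had an adjusted p of 6.23e-15, and adjusted p = 0.106 with an estimated correlation. Oxidative stress (NRF2) genes rose in 8 of 19 cases (9 adjusted over the list alone), with Sqstm1, an autophagy receptor, at 1.94-fold and Nfe2l2, the NRF2 gene, at a log2 change of 0.59. NRF2 genes as a list had an adjusted p of 0.00399, and adjusted p = 0.106 with an estimated correlation. Autophagy and lysosome genes rose in 11 of 23 cases (13 adjusted over the list alone), with Gabarapl1 at 1.83-fold. Autophagy genes as a list had an adjusted p of 0.00044, and adjusted p = 0.106 with an estimated correlation. Endoplasmic reticulum chaperones did not pass as a list (adjusted p = 0.155): 4 of 20 rose and 7 fell (4 and 7 adjusted over the list alone). Edem1 and Herpud1, both of ER-associated degradation, were 1.93-fold and 1.79-fold higher, and Creld2 and the co-chaperone gene Dnajb9 were 1.55-fold and 1.54-fold lower. Heat shock proteins did not pass (adjusted p = 0.893; 3 rose and 3 fell of 15, 4 and 3 adjusted over the list alone). Targets of p53 did not pass (adjusted p = 0.0696; 7 rose and 2 fell of 19, 8 and 3 adjusted over the list alone), but passed without DMSO replicate 1 (adjusted p = 0.0451). Ribosomal protein genes rose in 10 of 13 cases (11 adjusted over the list alone), a call that ended with quantile normalization (adjusted p = 0.187). Ribosomal proteins as a list had an adjusted p of 0.0021, and adjusted p = 0.52 with an estimated correlation. Ribosome biogenesis genes did not pass (adjusted p = 0.182; 7 rose and 3 fell of 28, 7 and 3 adjusted over the list alone), with the nucleolar gene Gnl3 at 1.43-fold higher.

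HIF targets fell in 13 of 19 cases at 12 h and 1 rose (13 and 1 adjusted over the list alone). HIF targets as a list had an adjusted p of 8.67e-06, and adjusted p = 0.106 with an estimated correlation. The member that rose was Ero1a, an oxidase of the endoplasmic reticulum (2.28-fold), and Egln1 was 2.59-fold lower. Glycolysis genes fell in 9 of 17 cases (10 adjusted over the list alone), with the phosphofructokinase gene Pfkl at 2.30-fold, Hk2 at 1.86-fold and the lactate dehydrogenase gene Ldha at 1.73-fold lower. Glycolysis genes as a list had an adjusted p of 0.000336, and adjusted p = 0.153 with an estimated correlation. In fatty acid oxidation 11 of 22 fell and 1 rose (12 and 2 adjusted over the list alone). Fatty acid oxidation genes as a list had an adjusted p of 0.00328, and adjusted p = 0.315 with an estimated correlation. The mitochondrial carnitine enzyme gene Cpt2 was 1.74-fold lower (adjusted p = 0.186 with the mean of probe sets), and Ppargc1a, a coactivator of mitochondrial genes, was 2.20-fold higher. Fatty acid and triglyceride synthesis moved down (adjusted p = 0.0392, and adjusted p = 0.62 with an estimated correlation), with 10 of 23 fallen and 5 risen (12 and 6 adjusted over the list alone). Pnpla3, a lipid droplet acyltransferase and hydrolase, was 2.90-fold lower and Srebf1, the regulator of lipogenesis, 1.67-fold lower. Gpd1 had a log2 change of -0.90 but 0.47 in another probe set. The synthesis call ended without DMSO replicate 1 (adjusted p = 0.0658), DMSO replicate 3 (0.136) or 12 h replicate 1 (0.125). Cholesterol synthesis moved up (adjusted p = 0.0054, and adjusted p = 0.579 with an estimated correlation, or 0.073 without DMSO replicate 2), with 11 of 20 risen and 1 fallen (11 and 2 adjusted over the list alone). Idi1 rose 1.91-fold and Cyp51 1.79-fold. Sc5d had a log2 change of 0.72, but -0.40 (adjusted p = 0.00792) and -0.17 in its other probe sets. Lss had 0.57, but -0.19 in another. Lipolysis and lipid droplet genes fell in 9 of 12 cases and 1 rose (9 and 3 adjusted over the list alone), with the monoglyceride lipase gene Mgll at 2.67-fold and the lipase inhibitor gene G0s2 at 2.06-fold lower. Lipolysis genes as a list had an adjusted p of 0.00044, and adjusted p = 0.125 with an estimated correlation. Branched-chain amino acid breakdown genes fell in 10 of 20 cases (10 adjusted over the list alone), with Pcca at 1.39-fold lower. Branched-chain amino acid genes as a list had an adjusted p of 0.0021, and adjusted p = 0.202 with an estimated correlation. Insulin signalling and FOXO genes fell in 13 of 21 cases and 2 rose (15 and 4 adjusted over the list alone), with Irs2 at 1.97-fold and Irs1 at 1.80-fold lower. Insulin and FOXO genes as a list had an adjusted p of 0.00171, and adjusted p = 0.153 with an estimated correlation. Oxidative phosphorylation did not pass (adjusted p = 0.606; 1 rose and 4 fell of 46, the same numbers adjusted over the list alone), but moved down after quantile normalization (adjusted p = 0.00681). The tricarboxylic acid cycle did not pass (adjusted p = 0.296; 1 rose and 3 fell of 18, the same numbers adjusted over the list alone). Ogdh had a log2 change of -0.53 but 0.44 in another probe set.

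**Figure D3:**
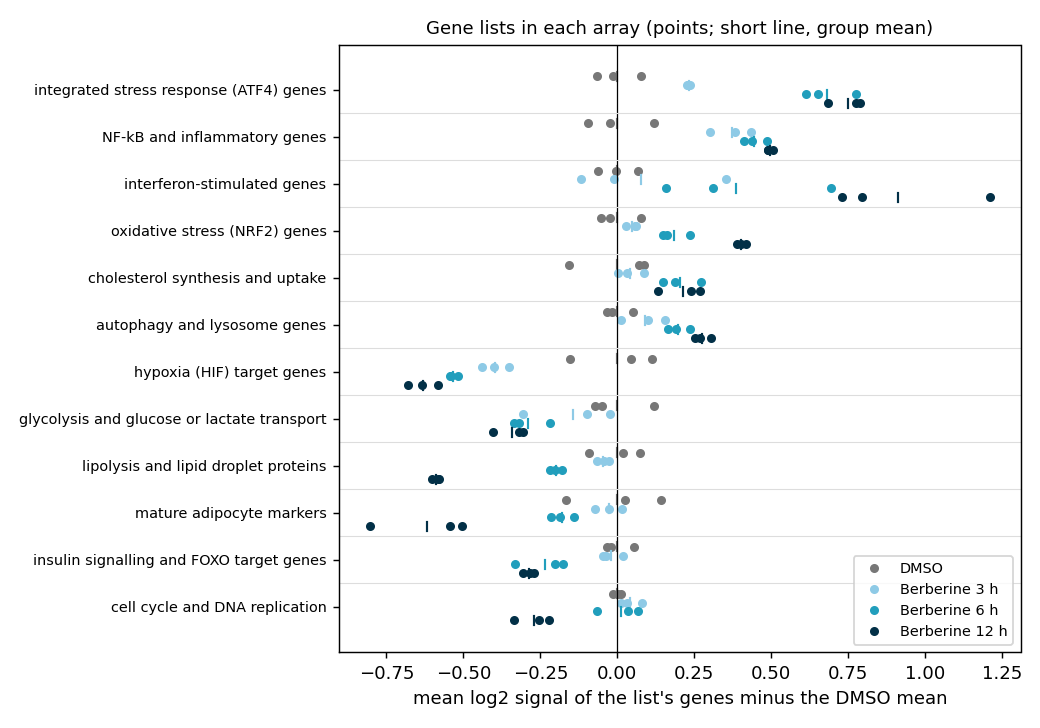
Mean log2 signal of the genes of 12 lists in each array minus the DMSO group mean (horizontal axis, log2 units), with points for arrays, short lines for group means and colours for the 4 groups (vertical axis, lists). For interferon-stimulated genes the 12 h arrays lie at 0.73 to 1.21, and the DMSO arrays at -0.06 to 0.07.

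NF-kB genes rose in 10 of 19 cases at 12 h and 1 fell (13 and 1 adjusted over the list alone), with Il6 at 3.21-fold, the cyclooxygenase gene Ptgs2 at 2.39-fold and Cxcl1 at 2.13-fold higher. NF-kB genes as a list had an adjusted p of 0.000336, and adjusted p = 0.153 with an estimated correlation. Interferon-stimulated genes rose in 15 of 19 cases (16 adjusted over the list alone), with Rsad2 and Ifit1, both antiviral genes, at 3.15-fold and 2.75-fold. Interferon-stimulated genes as a list had an adjusted p of 6.07e-07, and adjusted p = 0.153 with an estimated correlation. Cell cycle and DNA replication genes fell in 11 of 24 cases and 1 rose (11 and 1 adjusted over the list alone), with the replication licensing gene Cdc6 at 2.01-fold and the cyclin gene Ccne2 at 1.99-fold lower. Cell cycle genes as a list had an adjusted p of 0.000554, and adjusted p = 0.153 with an estimated correlation. Clock genes rose in 4 of 17 cases and 1 fell (5 and 1 adjusted over the list alone). Clock genes as a list had an adjusted p of 0.00758, and adjusted p = 0.213 with an estimated correlation. Dbp was 2.76-fold and Nr1d2 2.29-fold higher, and Npas2, a partner of the activator BMAL1, was at least 1.55-fold lower (adjusted p = 0.014, or 0.0581 without DMSO replicate 3). Immediate early genes did not pass (adjusted p = 0.643; 5 rose and 5 fell of 22, 6 and 6 adjusted over the list alone), with Atf3 higher and Egr2 at least 1.97-fold lower. Glucocorticoid-induced genes did not pass (adjusted p = 0.874; 4 rose and 5 fell of 17, 5 and 6 adjusted over the list alone), with Angptl4, a lipase inhibitor, at 2.27-fold lower. AMPK subunits and mitochondrial biogenesis factors did not pass (adjusted p = 0.35; 4 rose and 1 fell of 16, 4 and 2 adjusted over the list alone). Nrf1 had a log2 change of 0.89 but -0.27 in another probe set. Aryl hydrocarbon receptor targets did not pass (adjusted p = 0.677; 1 rose and 2 fell of 5, the same numbers adjusted over the list alone). Aldh3a1 was 1.86-fold lower, and Ahr, at 0.53, had -1.11 in another probe set.

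Mature adipocyte markers fell in 11 of 17 cases at 12 h and 1 rose (11 and 3 adjusted over the list alone). Adipocyte markers as a list had an adjusted p of 0.000336, and adjusted p = 0.153 with an estimated correlation. The glycerol channel gene Aqp7 was 1.94-fold lower, and Cebpa, a regulator of fat cell differentiation, had a log2 change of -0.59. The leptin gene Lep was at least 2.00-fold lower (adjusted p = 0.0227, or 0.0662 without DMSO replicate 1, 0.0521 without DMSO replicate 3 and 0.083 without the intensity trend). Adipokines did not pass (adjusted p = 0.762; 5 rose and 6 fell of 15, 6 and 6 adjusted over the list alone). Fibroblast and preadipocyte markers did not pass (adjusted p = 0.819; 4 rose and 4 fell of 17, 5 and 4 adjusted over the list alone), with Acta2 at 1.47-fold higher and Ccn5 at 1.60-fold lower. Macrophage markers did not pass (adjusted p = 0.704; 1 rose of 6, 1 adjusted over the list alone), with Cd14 at 1.30-fold higher. Brown and beige adipocyte markers did not pass (adjusted p = 0.982; 1 rose and 3 fell of 8, 2 and 3 adjusted over the list alone). Of the endothelial markers 2 were tested, too few for a list test, with log2 changes of -0.97 for Kdr (adjusted p = 0.383) and 0.06 for Egfl7 (adjusted p = 0.944). Median, mean and test differed in sign for macrophage markers (median -0.10, mean -0.24, test up), brown and beige markers (0.11 and 0.17, test down) and glucocorticoid genes (0.10 and -0.13, test down), and for heat shock proteins (median -0.10, test up). Among the single genes named in advance, Fasn, the fatty acid synthase, was 1.72-fold lower, the resistin gene Retn 1.42-fold, and Slc2a1 1.32-fold lower. Cyp1b1 was 1.17-fold lower (adjusted p = 0.0385) and Arrdc4 1.26-fold lower (adjusted p = 0.0434, or 0.0672 after quantile normalization). For Cyp1b1 it was 0.088 and 0.108 without DMSO replicates 2 and 3 and 0.095 and 0.197 without 12 h replicates 1 and 3. For Arrdc4 it was 0.14 and 0.12 without DMSO replicates 2 and 3 and 0.117, 0.103 and 0.0509 without 12 h replicates 1, 2 and 3. Pnpla2, the main triglyceride lipase, was 1.28-fold lower in the probe set used and had a log2 change of 0.16 in another. Adipoq (0.25, adjusted p = 0.0736, or 0.000978 without DMSO replicate 3), Pparg (-0.08, adjusted p = 0.411), the insulin receptor gene Insr (-0.22, adjusted p = 0.0974) and Txnip (-0.17, adjusted p = 0.0788) were not called. Fgf21, Gdf15 and Ucp1 were not tested because too few arrays reached the threshold.

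The berberine times were also compared with each other. As in the contrasts with DMSO, berberine and time in culture cannot be separated here. From 3 to 6 h 284 genes changed, 145 higher and 139 lower. Trib3 rose 2.23-fold and Ddit3 2.08-fold (with a log2 change of -0.76, adjusted p = 0.675, in a dimmer probe set), and Hcar2 was 1.70-fold lower. In this step 19 of 34 integrated stress response genes rose (list adjusted p = 7.19e-25, adjusted p = 0.0321 with an estimated correlation). From 6 to 12 h 690 genes changed, 304 higher and 386 lower. Mreg was 3.07-fold, Stbd1 2.70-fold and Hmox1 2.52-fold higher, and Angptl8, a regulator of lipoprotein lipase, was 2.66-fold, Pck1 2.56-fold and Pnpla3 2.51-fold lower. Here 9 of 17 mature adipocyte markers fell (list adjusted p = 4.35e-07, adjusted p = 0.0671 with an estimated correlation), as did 9 of 24 cell cycle genes (list adjusted p = 3.6e-09, adjusted p = 0.0671 with an estimated correlation). From 3 to 12 h 2150 genes changed, 972 higher and 1178 lower, among them Hmox1 (4.35-fold higher) and Pck1 (4.39-fold lower). The count from 3 to 6 h was 99, 116 and 85 without 3 h replicates 1, 2 and 3, 107 and 97 without 6 h replicates 2 and 3, 60 without the intensity trend and 146 with the mean of probe sets. From 6 to 12 h it was 443 and 376 without 6 h replicates 1 and 2, 450, 435 and 410 without 12 h replicates 1, 2 and 3, and 296 without the trend.

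Genes called at 1 time were often called in the same direction at a later one. At 3 and 6 h 113 genes rose and 87 fell at both, where independent lists would share 9.56 and 6.91. At 3 and 12 h the shared numbers were 114 and 86 against 18.1 and 14.4, and at 6 and 12 h 757 and 713 against 120.2 and 123.3. Unchanged groups simulated against the same DMSO arrays shared 0 genes in each pair of times, but they had at most 1 call per time, so this leaves the overlap without a useful chance value. The correlation of log2 changes across genes, which are not independent replicates, was 0.53, 0.49 and 0.65 for these pairs, against 0.50 in the simulation, and so no higher at 3 and 12 h. The covariance was 0.0745, 0.0828 and 0.127 against 0.0552, 0.0550 and 0.0553, a difference of 0.0194, 0.0277 and 0.0716. The 3 DMSO arrays are too few to split, so part of the overlap beyond independent lists may come from the shared controls. Of the 3699 genes called at any time, 190 were called at all 3 times, 1283 at 6 and 12 h and not 3 h, and 1942 at 12 h alone, though a call at a single time does not show that the times differ.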

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

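The counts over other splits of the arrays and most tests of opposite probe sets were planned; the comparison of opposite genes with the false calls allowed, and the tests of whole-array scaling and of the genes kept without _s_at and _x_at probe sets, of a single interferon array and of clock phase were chosen after the result was seen.

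The berberine groups differed between times in 284 genes (6 against 3 h), 690 genes (12 against 6 h) and 2150 genes (12 against 3 h), by limma's test of the contrast between the times. With 1 DMSO group of unstated duration, effects of berberine and of time in culture cannot be separated in these differences. Each contrast of 3 arrays with 3 allows 10 splits, too few for a share under 0.05; the highest count in another split was 1 for 3 h against DMSO (231 genes in the real split) and 1 for 6 h (1726), and 0 for 12 h (3426) and for the contrasts between times, and only the real split, 1 of 10, reached its count. For the F test over 4 groups, 1 of 100 groupings, the real one, reached 3045 genes, and the highest other gave 506. A random grouping of these arrays is thus an unlikely source of the count. Chance differences between cultures stay open, since the labels do not say that the arrays of a group came from separate cultures. A few genes were called in opposite directions at different times. H1f2, a linker histone gene, was higher at 3 h (0.25) and lower at 12 h (-0.39), a log2 difference of -0.64. Abcc4 (-0.44 at 6 h and 0.47 at 12 h, difference 0.91), Ier3 (-0.36 and 0.35, difference 0.71) and Maff (-0.44 and 0.42, difference 0.87) were lower at 6 h and higher at 12 h.

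Lists that differed between times by camera at the preset correlation are given by their mean log2 difference. From 3 to 6 h these were integrated stress response (0.45), glycolysis (-0.15), HIF (-0.14), oxidative phosphorylation (0.063), cholesterol synthesis (0.16), interferon-stimulated (0.31), clock (0.087), insulin signalling (-0.22) and ribosomal protein genes (0.13). From 6 to 12 h they were integrated stress response (0.069), oxidative phosphorylation (-0.11), tricarboxylic acid cycle (-0.089), fatty acid oxidation (-0.17), lipolysis (-0.39), branched-chain amino acid (-0.10), mature adipocyte (-0.44), interferon-stimulated (0.52), NRF2 (0.22) and cell cycle genes (-0.28). From 3 to 12 h they were integrated stress response (0.52), glycolysis (-0.20), HIF (-0.24), fatty acid oxidation (-0.23), cholesterol synthesis (0.17), lipolysis (-0.54), branched-chain amino acid (-0.16), mature adipocyte (-0.59), interferon-stimulated (0.84), NRF2 (0.35), cell cycle (-0.31), insulin signalling (-0.27) and autophagy genes (0.19). With an estimated correlation the integrated stress response from 3 to 6 h was the one that passed (adjusted p = 0.0321).

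Outside the gene tests, 20, 277 and 536 probe sets with no symbol or several were called against DMSO at 3, 6 and 12 h, of 2735 kept probe sets with none and 612 with several. At 12 h 336 of the called probe sets had no symbol and 200 had several.

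Of 1011 genes with at least 2 probe sets called at 12 h, 142 (14.0%) had calls in opposite directions, as had 32 of 346 (9.25%) at 6 h and 0 of 26 at 3 h; Sptlc2, a subunit of the enzyme that starts sphingolipid synthesis, had 0.79 and -0.84. Probe sets whose ending, _s_at or _x_at, marks possible binding to other genes' transcripts could not account for most of the 142 genes. Such binding by probe sets with other endings was not tested. Without the _s_at and _x_at probe sets 119 of the 142 still had opposite calls, which is 16.1% of the 739 genes then left with at least 2 called. Nor could a scaling of whole arrays that quantile normalization removes, since 133 of the 142 still had opposite calls after it. At an adjusted p under 0.001, 12 of 272 genes (4.41%) stayed opposite at 12 h, and 0 of 44 at 6 h. The 12 genes are too close to the planned limit of 10 to decide about false calls as the cause of all 142. False calls could not account for these 12, where 1.82 false calls were allowed among all calls. The brighter probe set rose in 67.6% of the genes (95% interval 59.2% to 75.2%), which leaves a bias with brightness open. Different 3' ends of the transcripts would be a biological explanation, which was not tested because probe positions were not used here.

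Interferon-stimulated genes rose in 7 of 19 cases at 6 h and in 15 of 19 at 12 h, with an adjusted p of 0.499 and 0.153 for the list with an estimated correlation. At 12 h a single array could not account for the rise, since the lowest 12 h array lay 0.66 above the highest DMSO array in the mean log2 signal of the list, against a DMSO range of 0.13. Induction of interferon transcripts may precede such a rise, but 4 of 10 interferon probe sets reached the threshold in the 3 arrays needed for a test. Mean log2 signals were 5.26 (Ifnb1), 5.06 (Ifng) and 4.56 (Ifna1), under the threshold of 5.77, and 6.14 (Ifnz). Of these 4, 0 were called higher by limma (Ifnb1 adjusted p = 0.326, Ifng adjusted p = 0.316), and the other 6 say nothing, so this stays open. An effect of berberine itself, the difference the design names, stays open and untested.

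Of 9 clock output genes, 3 were called higher at 12 h (Dbp, Nr1d2 and Per3) and the other 6 were not called, while the time of the DMSO cells is not given. If the groups had been harvested at different phases of the cell clock, genes of opposite phase might move apart. At 12 h the median log2 change was 0.30 over 9 output genes and 0.01 over 5 genes of opposite phase. The difference was 0.29, with a 95% interval of -0.20 to 1.81 from resampling these genes. That interval spans 0 and measures the spread over a few genes, not between arrays. Phase and berberine cannot be told apart here, since each time is a group of its own.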

How the results depend on the processing

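Every alternative given here was planned. The counts of genes and lists stayed within 1.5 times their values under quantile normalization, no filter, dim values raised to the threshold and, for genes, a pseudocount of 16, the filter at the 75th percentile and the fit of only the 2 groups compared; quantile normalization shared 221 of 231, 1550 of 1726 and 3278 of 3426 calls at 3, 6 and 12 h in the same direction. Without the intensity trend the counts were 93 (3 h), 60 (6 against 3 h) and 296 (12 against 6 h), and with the mean of a gene's probe sets 114 (3 h), 1099 (6 h) and 146 (6 against 3 h); the cause was not tested. Over all kept probe sets, more units than genes, 2627 (6 h), 5847 (12 h), 3430 (12 against 3 h) and 4861 (F test) were called. With an estimated correlation 0 lists passed at 3, 6 and 12 h, instead of 9, 13 and 17. The estimates reached 0.658 (ribosomal proteins), against the preset 0.01. Lists with estimates under 0.01 also had higher unadjusted camera p-values. These went from 0.0018 to 0.011 for NRF2 genes at 12 h (estimate 0.00339) and from 0.00273 to 0.0116 for p53 targets at 6 h (-0.0241). A higher correlation is thus not the whole cause, and a list that fails with an estimated correlation need not have correlated members. The rest of the cause was not tested.

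Leaving out each array, which leaves fewer arrays, gave 117 to 266 genes at 3 h (117 without DMSO replicate 1, 137 and 126 without 3 h replicates 1 and 2), 1116 to 1523 at 6 h (1116 without DMSO replicate 1, 1140 without 6 h replicate 2), 2683 to 3098 at 12 h, 2340 to 2951 by the F test, 85 to 229 for 6 against 3 h (99, 116 and 85 without 3 h replicates 1, 2 and 3, 107 and 97 without 6 h replicates 2 and 3), 376 to 539 for 12 against 6 h (443 and 376 without 6 h replicates 1 and 2, 450, 435 and 410 without 12 h replicates 1, 2 and 3) and 1599 to 1900 for 12 against 3 h. Lists numbered 5 to 13 at 3 h (5 without 3 h replicate 2), 12 to 14 at 6 h and 16 to 17 at 12 h. Of 1488 values for 248 pairs of gene and contrast, 167 lost and 4 gained their call, and 0 turned. The 248 pairs were a selection from those that the naming rule took. These numbers therefore do not show how often calls ended among all genes of the rule.

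Same-numbered arrays did not deviate together (correlations from -0.04 to 0.03 over 18 pairs), and 7 of 12 arrays were closest on average to their own number. With the replicate number as a block the counts were 221 (3 h), 1713 (6 h), 3398 (12 h), 275 (6 against 3 h), 677 (12 against 6 h), 2139 (12 against 3 h) and 2974 (F test), with 9, 13 and 17 lists; 6 named genes lost and 1 gained their call.

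After quantile normalization Cox6c at 6 h went from 0.23 to -0.0088, Fabp4 from 0.29 to 0.00 and the oxidative phosphorylation list from 0.08 to -0.028. With the mean of probe sets Fabp4 at 6 h was -0.15 and Ahr at 12 h -0.29. Among 166 other probe sets of named genes, 62 lost the call and 18 had the opposite sign: Narf 0.33 and Mxi1 0.031 at 3 h; Ccdc180 0.19, Cox6c -0.030 and Fabp4 -0.75 and -0.57 at 6 h; at 12 h Pi15 0.48, Ogdh 0.44, Gpd1 0.47, Sc5d -0.17 and -0.40, Lss -0.19, Mccc2 0.015, Rpl7 -0.16, Nrf1 -0.27, Ahr -1.11 and Pnpla2 0.16; and Ddit3 -0.76 for 6 against 3 h. The cause was not tested. Of the same 248 selected pairs, 44 lost their call without the intensity trend and 40 with the mean of probe sets. With only the 2 groups compared 24 lost it, without the filter 18 and with quantile normalization 11. Raising dim values to the threshold ended 15 calls. In 10 of these the log2 change stayed the same, and in 5 it moved, where signal over background is the limit, as for Ccl20 at 3 h (adjusted p = 0.107).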

Other observations

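All family tests given here were chosen after members had been seen to fall. They are 4 families at 3 times, 12 tests, adjusted over the 4 families within a time and not over the times, and the families were picked because Spry4, Dusp6, Srsf2, Cavin1 or Ppp1r3b had been noticed.

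Members of several groups of genes that were not among the fixed lists changed with berberine, though Egr1, Fosl1 and Ier3 of the ERK group also stand on the fixed immediate early list, which did not pass at any time. The ERK feedback family held ERK-induced genes such as Egr1 and Fosl1 as well as genes that feed back on growth factor signalling. Its members fell in 3 of 14 cases at 3 h, 6 at 6 h and 7 at 12 h, where 2 rose. At 12 h Spry1, Spry2 and Spred1 were not called (log2 changes of 0.15, 0.07 and 0.26), and Spred2 rose (0.32). Of 11 genes of serine- and arginine-rich splicing factors, 6 fell and 1 rose at 12 h, with Srsf2 at a log2 change of -1.02, Srsf3 at -0.78 and Srsf6 at -0.64. Of 19 glycogen genes, 8 fell and 3 rose at 12 h: the phosphatase subunits Ppp1r3b, Ppp1r3c and Ppp1r3d had -1.33, -1.30 and -1.22 and the glycogen synthase gene Gys1 had -0.87, while the glycogen-binding Stbd1 had 1.93. Of 7 genes of the caveola coat, 3 fell at 12 h, Cavin1 (-0.89), Cavin2 (-0.95) and Ehd2 (-0.57), while the median of the 7 was 0.02 and turned to -0.17 after quantile normalization.

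A hypothesis is that the ERK feedback family is lower as a whole soon after berberine. Its camera test gave an adjusted p of 0.0125 at 3 h, 0.0383 at 6 h and 0.135 at 12 h with an estimated correlation. Without the 3 members already named by the rule these values were 0.17, 0.185 and 0.758, a check added once the full family had passed. At the preset correlation the full family had 6.13e-05, 0.0018 and 0.0829, and 0.0243, 0.0654 and 0.74 without those members. The 2 correlations part at 3 h, so the hypothesis stays undecided. At the preset correlation the splicing family passed at 3, 6 and 12 h (adjusted p = 0.00959, 0.00371 and 0.0271), the caveola family at 12 h alone (0.0962, 0.174 and 0.0433) and the glycogen family at 6 and 12 h (0.0962, 0.0244 and 0.0332). After quantile normalization the caveola family passed camera as lower at 3, 6 and 12 h (0.0166, 0.00629 and 0.00788). Without its 3 members already named the glycogen family did not pass (0.68, 0.159 and 0.0547). The estimated correlation gave 0.135 for each of these families at 12 h, and 0.134 was the lowest at any time. The rule for a family was made stricter after results had been seen, first by asking for the estimated correlation and then for a pass without members already named. That last step took 0 members out of the splicing and caveola families, so it was no check of them. Under the stricter rule a change of these families as groups may be no more than the change of some members.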
